A study of Mus musculus with 8 samples.

How the data were processed

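The series holds 8 RNA-seq libraries of mouse megakaryocytes, 4 from hydrogel culture and 4 from liquid culture, and 1 table of gene counts covering all of them. The values are raw counts per gene as deposited by the authors, whole numbers with no normalization. Per the labels' protocols, polyA RNA was turned into stranded libraries. Per the submitters' processing notes, bcl2fastq, STAR 2.7.10b and HTSeq 0.13.5 were used with genome build GRCm39; the annotation release and the counting settings are not given in the sources used here. Without the strand setting, genes that overlap an antisense partner are uncertain, as are near-identical copies. Groups and replicate numbers came from the sample labels. The table lists 27679 genes, and 2 stray text lines that name no gene were left out. Symbols were matched from the identifiers with a GENCODE annotation of another build, from which no coordinate is printed: 26534 identifiers had a symbol and 1145 did not, the latter with at most 0.135% of a library's counts. The 11 symbols shared by several identifiers were not named, and 0 sample columns were left unused.

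Totals ranged from 27012172 to 49281611 counts per library. Genes were filtered with edgeR's filterByExpr by group, which kept 13845, scaled by TMM and tested with edgeR's quasi-likelihood test (edgeR 4.0.16, R 4.3.3), with culture as the only term and Benjamini-Hochberg adjustment at 0.05. The standard error of a log2 fold change is its size divided by the square root of the F statistic. CPM are TMM-scaled, given as mean ± SD over 4 libraries. Gene lists with at least 5 tested members, 42 of 44 (33 pathway and 11 cell type lists), were tested against the other genes with camera (limma 3.58.1) at a preset correlation of 0.01, and again with an estimated correlation, and each list by itself with fry. A list's score in a library is the mean over its members of log2 CPM (prior count 2) centred on each gene's mean. Figures were drawn with matplotlib 3.10.9, and tables were handled in Python 3.11.15 with pandas 2.3.3 and numpy 2.4.6.

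The lists, the tests and the rule for named genes were set before the data were examined. Named were the 12 genes with the largest rise and the 12 with the largest fall among those that passed, had at least 2 CPM in the higher group and did not overlap between groups (predicted genes, Rik clones and pseudogenes left out); up to 4 passing members of each list with the smallest adjusted p; and a panel of 20 genes named whether or not they passed. Values of a few genes that meet the rule are not reported here. Alternatives set in advance were DESeq2's size factors, upper-quartile scaling, library totals alone, no low-count filter, at least 1 CPM in 4 libraries, DESeq2 (1.42.0), limma-voom, the replicate number as a block, thinning to the smallest library, an adjusted p under 0.01, fry in place of camera, and each library left out. Leaving out both hydrogel 1 and liquid 2, and the macrophage score as a covariate, were added after seeing the data.

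The scripts were tested on simulated counts for the comparison of hydrogel against liquid, 13845 genes with known changes in a seeded subset. The edgeR test recovered 43.3% of genes changed 1.5-fold, 83.6% of those changed 2-fold and 98.5% of those changed 4-fold, with 5.85% of its 171 calls false. Limma-voom had 5.99% false among 167 calls. DESeq2 had 17.0% false among 224 calls, because its p-values under 0.001 were more frequent among unchanged genes (0.294%) than edgeR's (0.104%). Its acceptance bound on false calls was set aside after this was seen, so its count of called genes is liberal here. Camera found the planted list and 0 of 20 unchanged lists. The genes were simulated independently of each other, whereas estimated correlations within the real lists ranged from −0.04 (stromal cells) to 0.95 (mitochondrially encoded genes). The simulation therefore does not measure camera's false calls on lists whose members vary together.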

Results

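Gene expression was measured by polyA-selected, stranded RNA-seq in megakaryocytes, the large polyploid marrow cells that release platelets, taken from wild-type C57BL/6 mouse bone marrow. Marrow cells depleted of lineage-positive cells were cultured for 3 days in liquid medium or in a hydrogel of 2% methylcellulose with a Young modulus of 30 to 60 Pa, and the larger, mature cells were then enriched on a BSA gradient. The series contrasts the soft three-dimensional milieu, which confines the cells mechanically, with ordinary liquid culture. Each condition had 4 libraries, described by the submitters as independent biological replicates. Library totals ran from 27012172 to 37059314 counts in hydrogel and from 28825468 to 49281611 in liquid, and 13845 of the 27679 listed genes had enough counts to be tested.

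Culture in hydrogel was accompanied by lower cholesterol synthesis transcripts, lower megakaryocyte receptor transcripts, and higher transcripts of macrophage markers, lysosomal genes, lipid export genes and antioxidant genes. Each of these lists was called in the gene set test with a preset correlation, and none with an estimated one. Fry called each of them, with adjusted p from 0.000164 for the antioxidant list to 0.0423 for the receptors. It tests a list by itself, so it does not ask whether the list moved more than the other genes. Of 25 cholesterol synthesis and uptake genes, 24 fell, with a median log2 change of −1.03, which is 2.04-fold lower. Of 28 megakaryocyte and platelet surface receptors, 19 fell and 0 rose (11 fell without hydrogel 2, and 0 with the macrophage score as a covariate, where the median log2 change was 0.19), while 19 of 24 monocyte and macrophage markers rose with a median log2 change of 1.96. The acute-phase gene Saa3 (ENSMUSG00000040026) had the largest rise among the genes selected for size of change, from 1.06 ± 0.539 CPM in liquid to 119 ± 40.4 CPM in hydrogel (SD, n = 4 each). Ndrg2 (ENSMUSG00000004558) fell 8.81-fold, to 11.4 ± 2.64 CPM.

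In total, 4052 genes passed edgeR's quasi-likelihood test at a Benjamini-Hochberg adjusted p of 0.05, which is 29.3% of those tested. Of these, 2096 were higher and 1956 lower in hydrogel, and 1381 changed at least 2-fold (954 higher and 427 lower). The split by direction depended on the scaling between libraries, since upper-quartile scaling gave 1755 higher and 2492 lower, and library totals alone 2280 higher and 1513 lower. The 4 hydrogel libraries lay wholly above or wholly below the 4 liquid libraries for 28.4% of tested genes, against 2.86% by chance. Without hydrogel 2 the count fell to 2700.

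Libraries of the same condition resembled each other more than libraries of different conditions, with Pearson correlations of log2 CPM of 0.978 to 0.992 within and 0.947 to 0.973 between conditions. The first principal component, with 65.1% of the variance, separated the conditions. A pair of libraries lay between the others on it: hydrogel 1 scored 16.8 where the other hydrogel libraries scored 46.0 to 52.3, and liquid 2 scored −17.0 where the other liquid libraries scored −53.1 to −47.4. The same pair stood apart in cell type markers. The mean centred log2 CPM of the monocyte and macrophage markers was 0.23 in hydrogel 1 against 1.17 to 1.22 in the other hydrogel libraries, and −0.07 in liquid 2 against −1.44 to −0.98 in the other liquid libraries. With both left out, a choice made after seeing the data that widens the difference by its construction, 5633 genes were called. With the macrophage score as a covariate in the edgeR fit, likewise chosen after seeing the data and sharing 79.7% of its variance with culture (variance inflation factor 4.92), 693 were called.

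**Figure D1:**
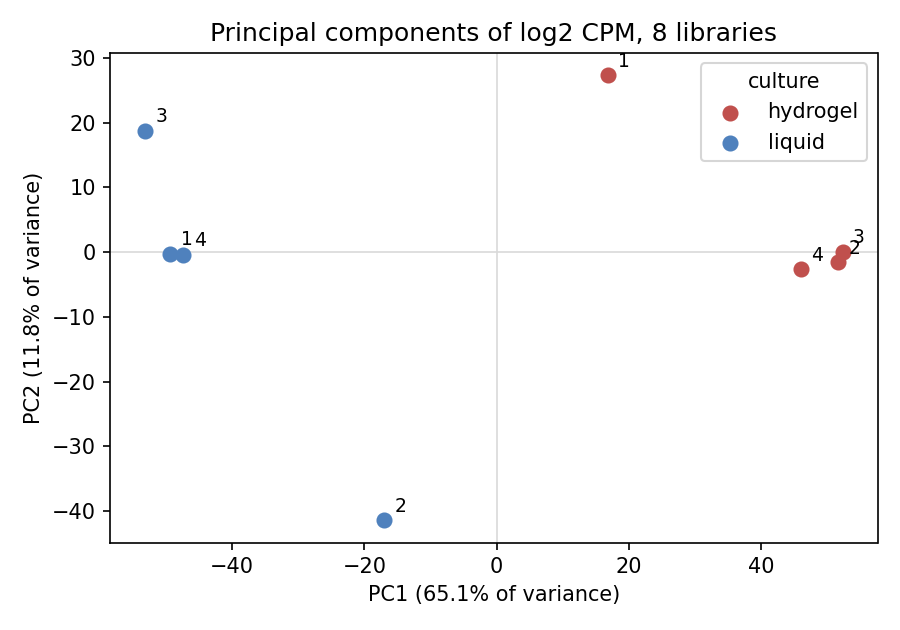
Principal components of log2 CPM in the 8 libraries, with component 1 (65.1% of the variance) on the x axis and component 2 (11.8%) on the y axis. Each point is a library, coloured by culture and numbered by replicate. All hydrogel libraries lie right of 0 and all liquid libraries left, with hydrogel 1 (16.8) and liquid 2 (−17.0) nearest the centre.

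Among the 12 largest rises, Cd5l, a secreted macrophage protein, went from 2.19 ± 0.808 to 42.8 ± 16.2 CPM, Bst1, a myeloid surface enzyme, from 0.350 ± 0.328 to 12.3 ± 4.49 CPM, and Stac2 from 0.445 ± 0.332 to 12.9 ± 4.90 CPM (SD, n = 4 each). Ptgfrn rose 26.2-fold, Gpr162 21.1-fold and Sirpb1c 23.7-fold, and Pira2 went from 0.249 ± 0.171 to 4.97 ± 2.28 CPM. Marco, a scavenger receptor of macrophages, had 6 reads over the 4 liquid libraries and 574 over the hydrogel libraries, Gpr83 had 5 and 418, Tarm1 had 6 and 457, and Muc20 had 8 and 317, so that the sizes of these 4 rises are poorly determined. Among the 12 largest falls, the transcription factor Npas4 went from 14.1 ± 2.94 to 1.67 ± 0.661 CPM, Lypd1 from 8.85 ± 1.89 to 1.06 ± 0.309 CPM, and Spon2 from 5.57 ± 1.42 to 0.549 ± 0.262 CPM. Fscn1, the actin bundler fascin, fell 10.3-fold, Fam196a 12.3-fold, Pik3c2g 11.6-fold, Chad 8.25-fold and Cd7 7.79-fold. The retinoid receptor gene Rxrg had 4 reads over the hydrogel libraries, all in hydrogel 1, and 300 over the liquid libraries. Ccr9 and Siglech, markers of plasmacytoid dendritic cells, had 13 and 29 reads in hydrogel against 389 and 399 in liquid. The adjusted p of these 24 genes in edgeR's test ranged from 3.22e-05 for Ndrg2 to 0.00203 for Siglech. None lost its call when any 1 library was left out, which their selection by size and by groups that do not overlap made likely. With the macrophage score as a covariate Sirpb1c (0.0822), Pira2 (0.133) and Pik3c2g (0.0887) lost theirs. Omission of 1 library changed the fold by over 1.5 times for Bst1 and Gpr162, whose log2 rises became 5.92 and 5.12 without liquid 2, where Bst1 stood at 5.17 and Gpr162 at 21.1-fold with all libraries. Likewise the log2 changes of Fam196a and Pik3c2g, −3.62 and −3.53, became −4.26 without hydrogel 3 and −4.25 without hydrogel 1. Those of Ccr9 (−4.78), Marco (6.67) and Muc20 (5.38) became −4.08 without liquid 2, 5.91 without hydrogel 4 and 6.87 without liquid 1, and that of Rxrg (−5.86) became −9.08 without hydrogel 1, where no hydrogel read was left and the size rests on the prior count.

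Cholesterol synthesis was the list with the smallest p in the gene set test at the preset correlation. With an estimated correlation its adjusted p equalled those of the antioxidant and matrix lists. In fry the antioxidant list had a smaller adjusted p (0.000164 against 0.000407). Acat2, which condenses acetyl-CoA, fell from 62.1 ± 4.11 to 28.3 ± 1.28 CPM (log2 change −1.13 ± 0.07 SE, adjusted p = 4.74e-05, edgeR), the mevalonate kinase gene Mvk fell by 1.08 ± 0.08, Hsd17b7 by 1.38 ± 0.10 and Dhcr7, of the last step to cholesterol, by 0.99 ± 0.08 on the log2 scale. All 4 lay lower in every hydrogel library than in any liquid library. With p adjusted over the list alone, 25 of the 25 fell. The members as a group lay below the other tested genes (camera with a preset correlation of 0.01, adjusted p = 2.38e-38), and with an estimated correlation the adjusted p was 0.101. Between 22 and 24 members fell when any 1 library was omitted, and 25 fell without both hydrogel 1 and liquid 2; with the macrophage score as a covariate 15 fell, with a median of −0.80. The list of lipid export genes and targets of LXR, the sterol-sensing nuclear receptor, went the other way. It also holds genes of fatty acid handling, such as Fabp4 and Fabp5, so it does not measure LXR activity alone. Of its genes, 10 of 18 rose and 0 fell (13 and 1 adjusted over the list alone), with a median log2 change of 1.16. The cholesterol exporter gene Abca1 rose from 26.0 ± 5.84 to 96.3 ± 12.1 CPM. The fatty acid binding protein genes Fabp4 and Fabp5 rose 10.4-fold and 5.93-fold, and the phospholipid transfer protein gene Pltp rose 6.72-fold. For this list camera's adjusted p was 4.93e-10 with the preset and 0.181 with an estimated correlation. The LXR list holds genes that macrophages express abundantly, and their marker score was higher in the hydrogel libraries, as given above; with that score as a covariate 5 rose, and Pltp was not called (log2 change 1.30, adjusted p = 0.0653).

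**Figure D2:**
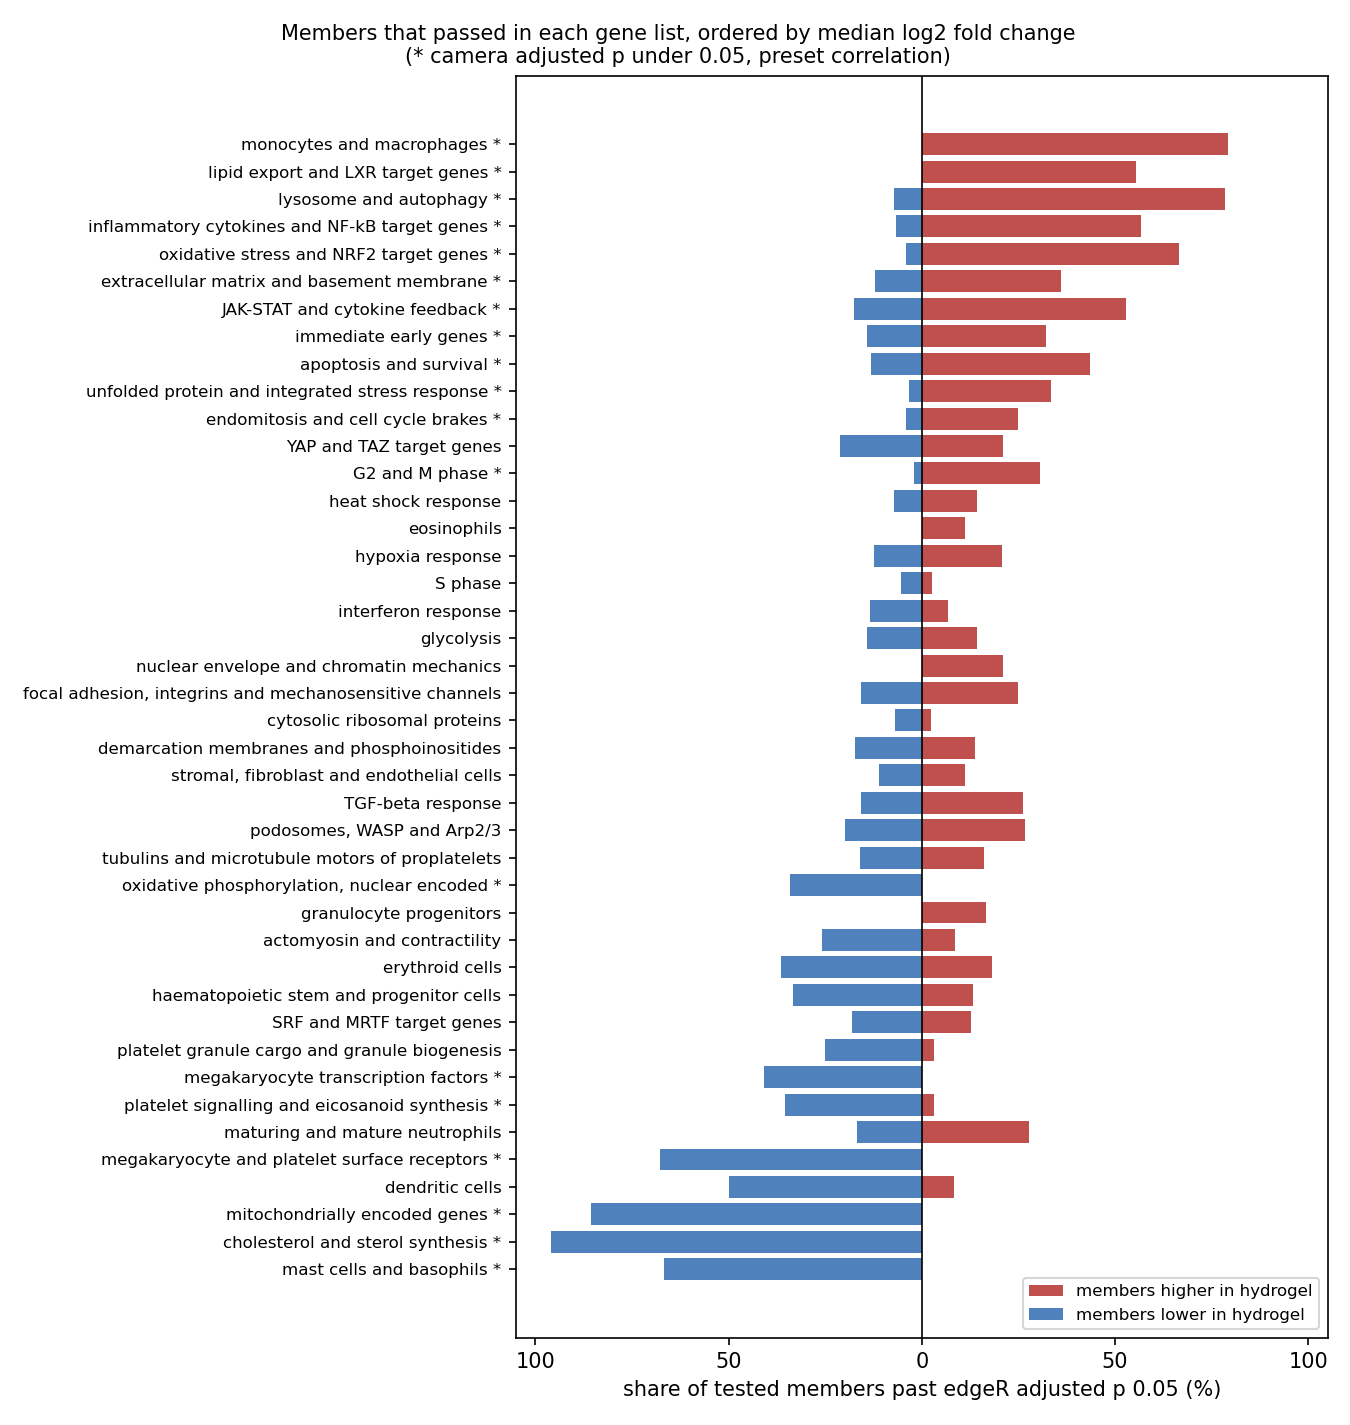
Share of the tested members of each gene list that passed edgeR's test, in percent, for the 42 lists with at least 5 tested members. Red bars to the right of 0 are members higher in hydrogel and blue bars to the left members lower in hydrogel; an asterisk marks lists with a camera adjusted p under 0.05 at the preset correlation, none of which passed with an estimated correlation. Cholesterol synthesis has 24 of 25 members lower and monocytes and macrophages 19 of 24 higher.

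Monocyte and macrophage markers rose by the largest median of the 44 lists. Lyz2, the lysozyme of myeloid cells, rose from 883 ± 238 to 3536 ± 945 CPM, Mpeg1 from 193 ± 109 to 1324 ± 442 CPM, Cd68 from 43.1 ± 22.6 to 296 ± 101 CPM and Spp1, osteopontin, from 29.1 ± 9.22 to 180 ± 71.8 CPM (SD, n = 4 each; edgeR adjusted p of 0.000554 to 0.00089). Adjusted over the list alone, 22 of the 24 rose. Camera's adjusted p was 2.87e-15 with the preset and 0.305 with an estimated correlation. The number that rose was 18 to 22 when any 1 library was omitted, and 23 without both hydrogel 1 and liquid 2.

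Lysosome and autophagy genes rose with them, 22 of 28 passing upward and 2 downward (22 and 2 adjusted over the list alone; median log2 change 0.80). They included the autophagy receptor Sqstm1 (1.63-fold), the lysosomal cholesterol transporter Npc1 (2.57-fold) and the proteases Ctsa (2.42-fold) and Ctsz (3.02-fold). Camera's adjusted p for the list was 1.15e-13 with the preset and 0.205 with an estimated correlation. Inflammatory cytokines and NF-kB targets had 17 of 30 higher and 2 lower (19 and 3 adjusted over the list alone), with a median of 0.79. Beyond Saa3, Bcl3 rose 5.93-fold, Tnfaip2 4.77-fold and Il1b, the gene of interleukin-1 beta, 1.73-fold, whereas Il6 fell to 0.520 ± 0.399 from 1.68 ± 0.549 CPM, a call lost in 4 of the 8 single omissions (adjusted p of up to 0.0948 without liquid 4). The adjusted p of camera was 1.93e-08, and 0.181 with an estimated correlation. Of the matrix genes, 9 of 25 rose and 3 fell, with the same counts adjusted over the list alone. Col18a1, a basement membrane collagen, rose 18.5-fold to 500 ± 121 CPM, the proteoglycan gene Vcan 9.80-fold, and the matrix metalloproteinase genes Mmp8 and Mmp14 11.3-fold and 5.37-fold. Camera gave this list an adjusted p of 0.00113, and 0.101 with an estimated correlation. Omission of liquid 3 raised the matrix genes that fell to 5, and 0 lysosome genes fell without hydrogel 2, 3 or 4 or liquid 1, 3 or 4. Under the macrophage covariate, 2 lysosome genes rose and 0 fell (median 0.32; Npc1, Ctsa and Ctsz not called, with adjusted p of 0.222 to 0.263), 6 inflammatory genes rose and 2 fell (0.25; Il6 not called, 0.535), and 7 matrix genes rose and 2 fell (0.34).

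**Figure D3:**
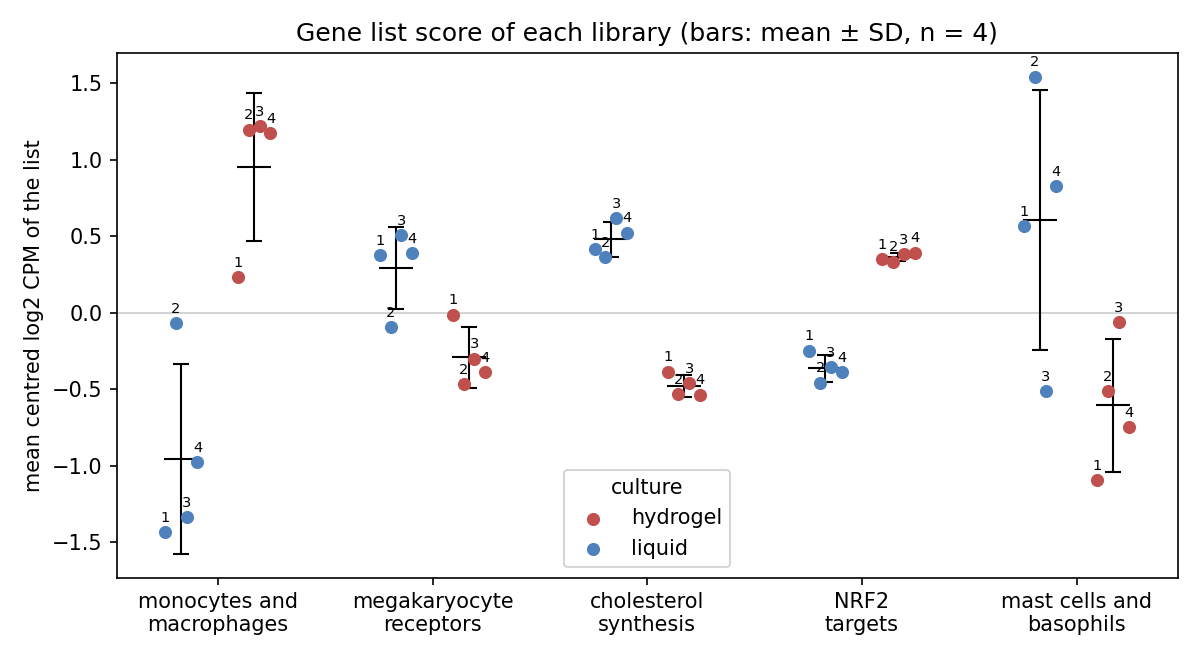
Mean centred log2 CPM per library of the gene lists shown, 1 point for each of the 8 libraries, hydrogel in red and liquid in blue. The macrophage score of hydrogel 1 (0.23) lies under those of the other hydrogel libraries (1.17 to 1.22), and that of liquid 2 (−0.07) above those of the other liquid libraries (−1.44 to −0.98).

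Markers of other marrow cells moved in differing directions. Mast cell and basophil markers had 8 of 12 lower and 0 higher (9 and 0 adjusted over the list alone; median log2 change −1.33), among them the mast cell protease Cpa3, which went from 41.8 ± 19.7 to 15.8 ± 6.42 CPM, and Il1rl1, which fell 2.73-fold; their calls were lost in 3 and 4 of the 8 single omissions, with adjusted p of up to 0.0582 without hydrogel 4 and 0.0819 without hydrogel 2. Il1rl1 also lost its call with limma-voom (0.106) and without both hydrogel 1 and liquid 2 (0.0643). Camera's adjusted p was 0.00113 with the preset and 0.631 with an estimated correlation, and fry, a rotation test of the list by itself, gave 0.0842. This result varied between libraries: only 1 member fell without hydrogel 2, without hydrogel 4 or without liquid 4, 3 fell without hydrogel 1, 4 without liquid 2 and 5 without liquid 1. Without hydrogel 1 and liquid 2 together 3 fell, and camera's adjusted p was 0.0777; with the macrophage score as a covariate 10 fell. Dendritic cell markers had 6 of 12 lower and 1 higher (6 and 4 adjusted over the list alone) with camera's adjusted p at 0.0931. Cd209a fell 6.74-fold and Clec9a 2.89-fold, along with Ccr9 and Siglech. The same test gave 0.00430 to 0.0451 when hydrogel 2, hydrogel 3, liquid 1, liquid 3 or liquid 4 was omitted, and 0.516 with the direction turned without both hydrogel 1 and liquid 2. The members that rose numbered 4 without hydrogel 1, 5 without liquid 2 and 0 without any other library; under the macrophage covariate 10 fell and 0 rose.

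Stem and progenitor markers had 2 of 15 higher and 5 lower (2 and 5 adjusted over the list alone; camera adjusted p = 0.247, and 0.0248 in fry). Mecom fell 4.02-fold and Flt3 3.84-fold, while Procr rose 9.71-fold and Cd48 3.73-fold. Erythroid markers had 2 of 11 higher and 4 lower (3 and 4 adjusted over the list alone; 0.965). Blvrb rose 2.22-fold, and the alpha-globin gene Hba-a1 fell 4.61-fold from a level of 6.43 ± 1.04 CPM. Mature neutrophil markers had 5 of 18 higher and 3 lower (5 and 5 adjusted over the list alone; 0.787): Mmp8, Il1f9 (4.75-fold) and the G-CSF receptor gene Csf3r rose while Ltb4r1 fell 1.51-fold. The log2 rise of Csf3r, 2.07, was 2.71 without liquid 2, which at 23.3 CPM lay above the 6.07 to 7.93 CPM of the other liquid libraries. Granulocyte progenitors had 2 of 12 higher and 0 lower, both before and after adjustment over the list alone (0.658); these were Cst7 (2.18-fold) and Igsf6 (3.32-fold). Eosinophil markers had 1 of 9 higher, and 0 adjusted over the list alone (0.787); this was Ear6, whose call was lost in 5 of the 8 single omissions, with an adjusted p of up to 0.133 without hydrogel 3. Stromal and endothelial markers had 1 of 9 higher and 1 lower, also adjusted over the list alone (0.658), where the VEGF receptor gene Kdr fell 2.36-fold and Cdh5 rose from 0.305 ± 0.0954 to 0.854 ± 0.284 CPM. Without both hydrogel 1 and liquid 2, 7 neutrophil markers rose and 2 fell, and that list was called with a camera adjusted p of 0.00541. Single omissions left 3 neutrophil markers that rose (without liquid 1 or liquid 4), and 1 (without hydrogel 4) to 6 (without liquid 3) that fell; 2 erythroid markers fell without hydrogel 2, 3 or 4. Too few members were tested for camera in the B cell list (Blnk rose 3.37-fold and Cd79b fell 1.45-fold, of 3 tested) and in the T and natural killer cell list (Cd4 rose 8.21-fold and Il7r 7.42-fold, of 4), and these counts were the same adjusted over the list alone. The median and camera's direction differed in sign for neutrophils (−0.59, upward) and granulocyte progenitors (−0.14, upward), but not without liquid 2, where the medians were 0.04 and 0.05, nor without both hydrogel 1 and liquid 2 (0.29 and 0.27). Under the macrophage covariate 11 neutrophil, 6 granulocyte progenitor and 2 eosinophil markers fell, and 4 erythroid markers rose. Procr (log2 change 0.80, adjusted p = 0.629), Cd48 (−0.28, 0.630), Cd4 (0.52, 0.606), Il7r (0.46, 0.338), Blnk (−0.35, 0.652), Csf3r (−0.12, 0.853), Igsf6 (−0.40, 0.429) and Ear6 (−0.34, 0.867) were then not called, nor were Hba-a1, Il1f9, Ltb4r1, Cd79b and Cdh5 (0.0514 to 0.564).

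Megakaryocyte receptors fell as a group, by a median of 0.60 on the log2 scale, 1.52-fold. The thromboxane receptor gene Tbxa2r went from 224 ± 33.4 to 128 ± 13.0 CPM, the podoplanin receptor gene Clec1b from 667 ± 157 to 299 ± 63.8 CPM, Gp1bb, of the von Willebrand factor receptor, from 50.1 ± 8.41 to 26.4 ± 4.48 CPM, and Treml1 fell 1.77-fold (edgeR adjusted p of 0.000922 to 0.00493). Adjusted over the list alone, 21 of 28 fell and 0 rose. The adjusted p of camera was 9.40e-08 with the preset and 0.583 with an estimated correlation. Itga2b and Itgb3, which encode the fibrinogen receptor and were among the most abundant transcripts, fell from 6352 ± 1122 to 3845 ± 830 CPM and from 9935 ± 2139 to 6468 ± 1313 CPM (adjusted p = 0.0165 and 0.0477). In hydrogel 1, Itga2b stood at 5077 CPM and Itgb3 at 8422 CPM, against 3346 to 3599 and 5689 to 6048 CPM in the other hydrogel libraries, where the macrophage marker score was higher. The count of receptors that fell was 11 without hydrogel 2, 12 without hydrogel 3 and 12 without hydrogel 4, 24 without liquid 2, and 25 without both hydrogel 1 and liquid 2. With the macrophage score as a covariate 0 fell and the median was 0.19, and Itgb3 lost its call with DESeq2's size factors (adjusted p = 0.0502).

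The platelet chemokine gene Pf4 fell 1.46-fold and the platelet tubulin gene Tubb1 2.15-fold (adjusted p = 0.0182 and 0.0216). Gp1ba and Vwf had log2 changes of −0.46 ± 0.18 and −0.43 ± 0.22 and did not pass (adjusted p = 0.0840 and 0.164). Both passed downward without hydrogel 1 (0.0425 and 0.0490), without liquid 2 (0.00601 and 0.0252) and without both (7.32e-05 and 5.83e-05), Gp1ba also with no low-count filter (0.0460), while Vwf passed upward with the macrophage score as a covariate (log2 change 0.74, 0.0288). Of granule cargo and granule biogenesis genes, 1 of 32 rose and 8 fell (2 and 8 adjusted over the list alone; camera adjusted p = 0.0515), with Stx11, of granule secretion, down 2.08-fold, Serpine2 down 1.49-fold, Pdgfb down 1.34-fold and Vipas39 up 1.38-fold. Of transcription factors, 9 of 22 fell and 0 rose (13 and 1 adjusted over the list alone; median −0.24; adjusted p = 0.00113, or 0.205 with an estimated correlation). Gata2 fell 2.46-fold, Hhex 1.64-fold, Ets1 1.43-fold and Mef2c 1.30-fold. Gata1 and Nfe2, drivers of late megakaryocyte maturation, fell 1.30-fold and 1.46-fold (0.0215 and 0.0206), and Fli1 had a log2 change of −0.25 ± 0.09 (0.0692), which passed with upper-quartile scaling (0.0328), without liquid 2 (0.0212) and without both hydrogel 1 and liquid 2 (0.00544). Platelet signalling and eicosanoid genes had 11 of 31 lower and 1 higher, also adjusted over the list alone (camera 0.000731, or 0.795 with an estimated correlation and 0.131 in fry). The phosphodiesterase gene Pde3a fell 2.03-fold, the calcium channel gene Orai1 1.46-fold, Prkg1 1.86-fold and Gng11 2.03-fold. The calls of these panel genes were lost in 4 to 6 of the 8 single omissions; without hydrogel 2, where it was highest, the adjusted p was 0.0609 for Itga2b, 0.138 for Itgb3, 0.0671 for Tubb1, 0.0693 for Pf4, 0.0694 for Gata1 and 0.0677 for Nfe2. Without hydrogel 2, 3 cargo genes, 4 transcription factors and 7 signalling genes fell; cargo genes that fell numbered 14 without hydrogel 1, 4 without hydrogel 3 or 4 and 5 without liquid 4, and those that rose 3 without liquid 2 and 4 without liquid 3; the transcription factors numbered 4 without hydrogel 3 and 5 without hydrogel 4 or liquid 3, and signalling genes 7 without hydrogel 4. Without liquid 2, 18 cargo genes and 20 signalling genes fell, and the cargo list passed camera (0.00272), as it did without hydrogel 1 (0.0210) and without both (0.000582). Once the macrophage score was a covariate, 2 transcription factors, 0 cargo genes and 0 signalling genes fell, and 6 cargo and 5 signalling genes rose; of the called genes named here, Gata2 alone kept its call.

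Genes of the contractile and force-sensing machinery moved in both directions. Of the actomyosin genes, 3 of 35 rose and 9 fell (3 and 11 adjusted over the list alone; camera adjusted p = 0.104). Myl9, the myosin light chain of megakaryocytes, went from 221 ± 89.3 to 82.3 ± 27.3 CPM, Tpm2 fell 2.59-fold and the GTPase gene Rhoc 1.96-fold, whereas the RhoA activator gene Arhgef2 rose 1.30-fold. Myh9, the heavy chain of non-muscle myosin IIA, had 4722 ± 1147 CPM in liquid and 5149 ± 860 CPM in hydrogel, a log2 change of 0.12 ± 0.19 (adjusted p = 0.661). Log2 changes of Myh10 (0.33 ± 0.27), Mylk (−0.18 ± 0.14), Flna (−0.14 ± 0.19), Actb (−0.15 ± 0.13) and Lmna (−0.16 ± 0.19) did not pass either, with adjusted p of 0.386 to 0.625. Without both hydrogel 1 and liquid 2, Flna (0.0250), Mylk (0.0351) and Lmna (0.0154) passed downward, and with the macrophage score as a covariate Lmna passed upward (log2 change 0.88, 0.0149). Of the SRF and MRTF targets, 5 of 39 rose and 7 fell, with the same counts adjusted over the list alone (0.104). Mrtfb rose 1.57-fold, and Tgfb1i1 and Actg1 both fell 1.64-fold. Actg1 had 929 reads in hydrogel and 1766 in liquid, against 857128 and 1093726 for Actb. How reads of near-identical copies were counted is not given, so the change of Actg1 is uncertain. The regulators Mrtfa (−0.02 ± 0.10) and Srf (−0.20 ± 0.08) did not pass, although Srf did with upper-quartile scaling (0.0336) and without liquid 2 (0.0436). Without liquid 2, 17 SRF and MRTF targets fell and both lists passed camera downward (0.0213 for actomyosin and 0.00282 for SRF and MRTF), as they did without both hydrogel 1 and liquid 2 (0.0291 and 0.00212); without hydrogel 2 or 3, 5 actomyosin genes fell, and 3 SRF and MRTF targets rose without hydrogel 2, 3 or 4 or liquid 1. Adding the macrophage covariate ended the calls of Myl9 (log2 change 0.44, 0.355), Tpm2, Rhoc, Arhgef2, Mrtfb, Tgfb1i1 and Actg1 (0.211 to 0.853) and left 0 actomyosin genes that rose or fell, and 1 SRF and MRTF target rose and 1 fell.

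The mechanosensitive channel gene Piezo1 rose from 53.3 ± 14.0 to 124 ± 24.3 CPM (adjusted p = 0.00138), a log2 rise of 1.22 that was 0.14 and not called with the macrophage score as a covariate (adjusted p = 0.652). It belonged to the focal adhesion, integrin and channel list, in which 8 of 32 rose and 5 fell (10 and 7 adjusted over the list alone; camera adjusted p = 0.747); Itgb2 and Itga4, integrins of leukocytes, rose 1.70-fold and 1.95-fold, and the kinase gene Src fell 1.59-fold. Podosome and Arp2/3 genes had 8 of 30 higher and 6 lower, likewise adjusted over the list alone (0.579), with Iqgap1 up 2.16-fold, Rac2 1.60-fold and Arhgap31 1.63-fold. Tubulins and microtubule motors had 5 of 31 higher and 5 lower, likewise adjusted over the list alone (0.965): Vash1, which trims the tubulin tail, rose 2.95-fold, Tubb6 2.02-fold and Tubb3 3.82-fold, and Tuba1a fell 1.70-fold. Genes of the demarcation membranes, the internal membrane store of platelets, had 4 of 29 higher and 5 lower (5 and 6 adjusted over the list alone; 0.579). Sept6 fell 2.11-fold and Fnbp1l 1.51-fold, and Sept9 and Pik3c2a rose 1.86-fold and 2.65-fold. Nuclear envelope genes had 4 of 19 higher and 0 lower, also adjusted over the list alone (0.260): vimentin (Vim) rose 4.44-fold, plectin (Plec) 2.55-fold, Syne3 1.53-fold and Tor1aip1 1.17-fold, whose call was lost without hydrogel 3 (adjusted p = 0.0689), hydrogel 4 (0.0630) and liquid 1 (0.0569) and with upper-quartile scaling (0.0549) or no low-count filter (0.0691). YAP and TAZ targets split evenly, 4 of 19 in each direction, also adjusted over the list alone (0.711); Myof rose 6.99-fold and Nt5e 2.02-fold, and Arhgef17 fell 2.45-fold and Amotl2 1.39-fold. TGF-beta genes had 5 of 19 higher and 3 lower (5 and 4 adjusted over the list alone; 0.906), with Id2 up 2.29-fold, Tgfbr1 up 1.73-fold, Smad7 down 2.45-fold and Ltbp2 down 3.08-fold. Medians were below 0 and camera's direction upward for the focal adhesion (−0.02), podosome (−0.09), tubulin (−0.12) and TGF-beta (−0.09) lists; that of focal adhesion was 0.05 without liquid 3. Under the macrophage covariate Vim (log2 change 0.16, adjusted p = 0.705), Plec (0.50, 0.273), Iqgap1 (0.32, 0.361), Myof (0.52, 0.273) and Itga4 (−0.05, 0.918) lost their calls, as did Src, Rac2, Tuba1a, Fnbp1l, Pik3c2a, Tor1aip1, Arhgef17, Amotl2, Id2 and Ltbp2 (0.0624 to 0.964), and of the focal adhesion, podosome, tubulin and TGF-beta lists 3, 4, 4 and 3 genes rose. The number of focal adhesion genes that fell was 8 without hydrogel 1, 13 without liquid 2 and 2 or 3 without any other library, and that of tubulin genes 1 without hydrogel 2, 10 without liquid 2, 2 without hydrogel 3 and 3 without hydrogel 4, liquid 1 or liquid 3. Likewise 3 podosome genes fell without hydrogel 2, 3 demarcation membrane genes fell without hydrogel 2, 3 or 4 or liquid 4 and 8 without liquid 2, 5 focal adhesion genes rose without liquid 4, 3 tubulin genes rose without hydrogel 2 or liquid 1, and 2 YAP and TAZ targets rose without hydrogel 2, hydrogel 3 or liquid 4.

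**Figure D4:**
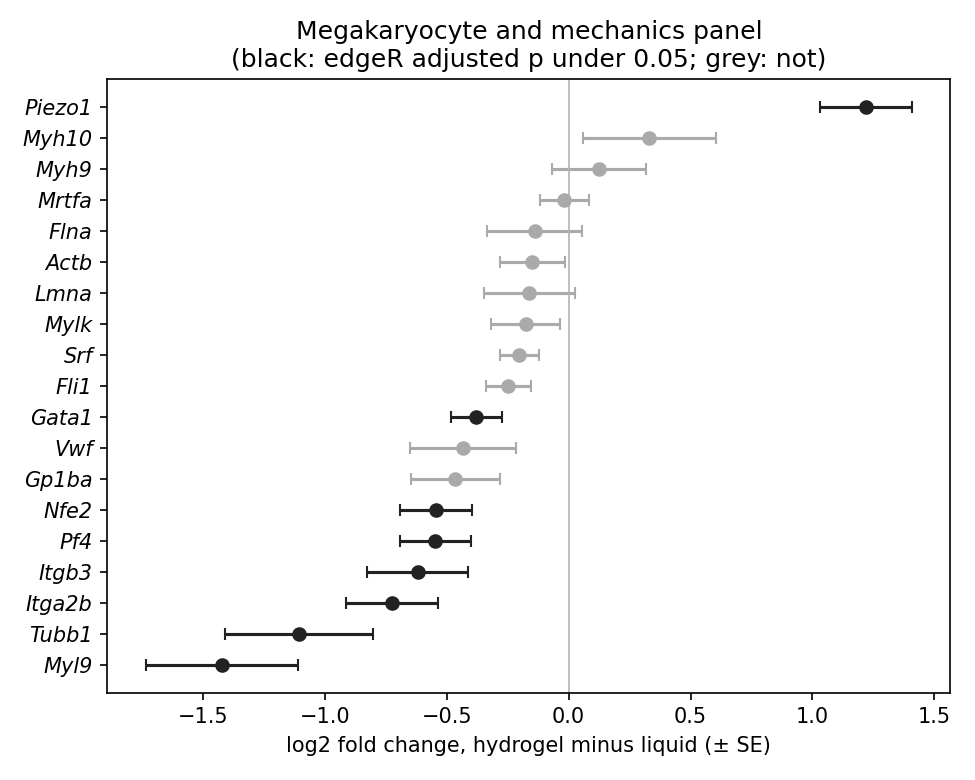
Log2 fold change, hydrogel minus liquid, of 19 megakaryocyte and mechanics genes chosen before the data were examined; bars are ± SE from edgeR with 4 libraries per condition. Black genes passed at an adjusted p of 0.05 and grey genes did not. Piezo1 is the one that rose (1.22 ± 0.19), and Myl9 has the deepest fall (−1.42 ± 0.31); with the macrophage score as a covariate neither was called (0.14 and 0.44).

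The antioxidant list, which joins oxidative stress genes and NRF2 targets, had 16 of 24 higher and 1 lower. Adjusted over the list alone these were 19 and 1, and the median log2 change was 0.57. The cystine transporter gene Slc7a11, with the smallest adjusted p among the named genes (1.46e-05), rose 6.25-fold, the glutathione peroxidase gene Gpx1 2.89-fold, the thioredoxin reductase gene Txnrd1 2.31-fold and the metallothionein gene Mt1 1.84-fold. Camera's adjusted p was 1.16e-13 with the preset and 0.101 with an estimated correlation. The unfolded protein and integrated stress response list had 10 of 30 higher and 1 lower, likewise adjusted over the list alone (0.000165, or 0.462 with an estimated correlation), including Cebpb (3.26-fold), Sesn2 (2.23-fold) and Slc3a2 (1.56-fold), partner of Slc7a11. Without liquid 4, 6 of them rose, and without both hydrogel 1 and liquid 2 the list was not called (camera adjusted p = 0.102). Antioxidant genes that rose under the macrophage covariate numbered 11, and those of the stress response list 8. Heat shock genes had 2 of 14 higher and 1 lower, likewise adjusted over the list alone (0.708); Hspd1 rose 1.27-fold, Hsp90aa1 1.24-fold, and Dnaja1 fell 1.27-fold, and these calls were lost without single libraries, with adjusted p of up to 0.0539 and 0.0787 for the first 2 without liquid 4 and 0.0523 for Dnaja1 without hydrogel 2, and of 0.0730 for Hsp90aa1 with upper-quartile scaling and 0.0567 for Dnaja1 with library totals alone. Under the macrophage covariate 0 heat shock genes were called.

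Transcripts encoded by mitochondrial DNA fell: 6 of 7 tested, also adjusted over the list alone, with a median of −0.80 (camera 0.000979, or 0.581 with an estimated correlation). mt-Nd5 went from 5878 ± 1573 to 3155 ± 315 CPM, mt-Cytb from 7469 ± 2052 to 4136 ± 435 CPM, and mt-Nd4 and mt-Nd2 fell 1.86-fold and 1.66-fold. Mitochondrial transcripts made up 1.98% to 2.48% of counts in hydrogel and 3.85%, 5.21% and 3.84% in liquid 1, 2 and 4, but 2.27% in liquid 3, within the hydrogel range. Without hydrogel 2, 2 of the 7 passed, and 4 without hydrogel 3; mt-Cytb and mt-Nd2 then had an adjusted p of 0.0514 and 0.0572 without hydrogel 2. Nuclear genes of oxidative phosphorylation had 14 of 41 lower and 0 higher (15 and 0 adjusted over the list alone; median −0.13; 0.00228, or 0.795 with an estimated correlation), including Cox5a (1.64-fold lower), Cox6a1 (log2 change −0.59), Cox6c (1.40-fold) and Ndufa2 (1.32-fold). Without hydrogel 2, 8 of them fell, and 9 without hydrogel 4; with the macrophage score as a covariate 0 fell, while 6 of the mitochondrially encoded genes did. Glycolysis genes had 3 of 21 higher and 3 lower, likewise adjusted over the list alone (0.893): the lactate exporter gene Slc16a3 rose 1.39-fold while Pkm, Pfkm and Aldoc fell 1.36-fold, 1.34-fold and 1.53-fold. Hypoxia genes had 5 of 24 higher and 3 lower (5 and 4 adjusted over the list alone; 0.626), with Nfil3 up 2.14-fold, Bhlhe40 2.06-fold and Ero1l 1.46-fold, and Narf down 1.43-fold. Ribosomal protein genes had 1 of 43 higher and 3 lower (0 and 3 adjusted over the list alone; 0.585), with Rpl15 down 1.36-fold, Rpl5 1.48-fold and Rpl13a 1.22-fold, and Rps2 up 1.18-fold; the calls of Rpl5 and Rpl13a were lost with library totals alone as scaling, and that of Rps2 with upper-quartile scaling, with no low-count filter and in 6 of the 8 single omissions. Without liquid 3, 6 ribosomal protein genes fell; 1 glycolysis gene rose without hydrogel 2, hydrogel 3, liquid 1 or liquid 4, and 5 fell without liquid 2. Under the macrophage covariate Pkm (log2 change −0.03, adjusted p = 0.946), Pfkm (0.08, 0.808), Aldoc (−0.37, 0.455), Nfil3 (0.84, 0.0933), Bhlhe40 (0.48, 0.208) and Narf (−0.13, 0.751) lost their calls, and 0 ribosomal protein genes were called.

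Of G2 and M phase genes, 15 of 49 rose and 1 fell (16 and 1 adjusted over the list alone; median 0.16), with Psrc1 up 1.66-fold, Gtse1 1.58-fold, Ckap2l 1.36-fold and Hmmr 1.32-fold. The adjusted p of camera was 0.00252, or 0.795 with an estimated correlation and 0.128 in fry; with the macrophage score as a covariate 0 rose and 1 fell, with a median of −0.23, and Rrm2 and Rfc2 of S phase were not called (0.916 and 0.381). Among single omissions, 8 rose without hydrogel 2, hydrogel 4 or liquid 4, and 24 without liquid 2. Of S phase genes, 1 of 38 rose (Rrm2, 1.45-fold) and 2 fell, Rfc2 by 1.21-fold among them, and 0 passed adjusted over the list alone (0.932). The call of Rfc2 was lost in 5 of the 8 single omissions, with an adjusted p of up to 0.0920 without hydrogel 3, and with library totals alone (0.127). Without liquid 2, 3 S phase genes rose. Whether the phases differed from each other was not tested. In the list of endomitosis regulators and cell cycle brakes, 6 of 24 rose and 1 fell, likewise adjusted over the list alone (0.00637, or 0.167 with an estimated correlation). These included both a driver of the G1 phase, cyclin D1 (Ccnd1, 4.11-fold), and the inhibitors Cdkn1a (3.07-fold) and Cdkn2a (from 0.249 ± 0.141 to 2.02 ± 0.465 CPM), as well as the p53 target Ccng1 (1.80-fold). Under the macrophage covariate 5 of the list rose and 1 fell, and without liquid 2, 3 fell.

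Apoptosis and survival genes had 10 of 23 higher and 3 lower (11 and 3 adjusted over the list alone; 0.00581, or 0.205 with an estimated correlation). They comprised promoters of cell death, Bcl2l11 (4.08-fold), Bax (1.41-fold) and Fas (2.13-fold), and the survival gene Mcl1 (1.47-fold). Without both hydrogel 1 and liquid 2 the list was not called (0.0721). JAK-STAT and cytokine feedback genes had 9 of 17 higher and 3 lower (9 and 4 adjusted over the list alone; 0.00530, or 0.452 with an estimated correlation): the receptor genes Csf2rb and Il4ra rose 4.96-fold and 2.83-fold, the feedback inhibitor Socs3 2.90-fold and the cytokine Osm 3.12-fold. Immediate early genes had 9 of 28 higher and 4 lower (10 and 4 adjusted over the list alone; 0.0254, or 0.631 with an estimated correlation). Atf3 rose 4.32-fold and Gadd45b 3.54-fold, and Btg2 fell 1.66-fold. Without hydrogel 4 or liquid 2 this list was not called (0.0589 for each), and 2 of its genes fell without hydrogel 2, hydrogel 3 or liquid 4. Given the macrophage covariate, 2 apoptosis genes rose and 0 fell, 3 JAK-STAT genes rose and 1 fell, and 0 immediate early genes rose and 1 fell (medians 0.21, 0.48 and 0.03), and Bcl2l11, Fas, Mcl1, Csf2rb, Osm, Atf3 and Gadd45b were not called (adjusted p of 0.116 to 0.544). Interferon genes had 2 of 30 higher and 4 lower (1 and 3 adjusted over the list alone; 0.893), where Ifih1 rose 1.33-fold and Ifi44, Cxcl10 and Oasl1, at 0.992 to 1.64 CPM in liquid, fell 5.98-fold, 2.49-fold and 2.86-fold. The calls of Cxcl10 and Oasl1 were each lost in 2 of the 8 single omissions, with an adjusted p of up to 0.0577 without hydrogel 3 and 0.0655 without hydrogel 4, and that of Oasl1 also without both hydrogel 1 and liquid 2 (0.0616), and those of Cxcl10 (0.0979) and Ifih1 (0.102) under the macrophage covariate. Without liquid 2, 5 interferon genes rose, without hydrogel 2, 1 rose and 1 fell, and without hydrogel 4, 2 fell. Of the 42 lists tested with camera, 19 were called with the preset correlation, 12 upward and 7 downward, and 0 with an estimated correlation; fry called 17. Among the 35 ways to split the 8 libraries into groups of 4, 11 called at least 19 lists, the real split included, and the highest other called 25.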

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

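The splits of the libraries were planned; all other tests here were chosen after the results were seen. A value was singled out where 1 library lay far from the other 3 of its condition, which chance alone gives in about 1 of 20 groups. Of 478 groups screened, over 194 genes, 42 lists and other values, 35 were singled out where chance gives about 23.9, although genes are not independent, 12 of them in hydrogel 1 and 7 in liquid 2.

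In hydrogel 1 stood apart Bst1 (5.62 CPM), Rxrg (0.110), Pik3c2g (0.493), Tbxa2r (147), Itga2b (5077), Itgb3 (8422), Gata1 (350.1), Lmna (687) and Clec9a (10.4), and the scores of macrophages (0.23), nuclear envelope (−0.0296) and granulocyte progenitors (−0.79). In liquid 2 stood apart Gpr162 (1.84 CPM), Piezo1 (74.2), Pik3c2a (8.81), Oasl1 (1.87), Igsf6 (37.6) and Csf3r (23.3), and principal component 1 (−17.0). In hydrogel 2 these were Npas4 (0.687 CPM), Tgfb1i1 (156) and Ero1l (69.9); in hydrogel 3 Arhgap31 (67.5 CPM), Cdh5 (1.28) and the ribosomal protein score (−0.0842). In hydrogel 4 they were Marco (10.2 CPM), Siglech (0.0647), Syne3 (50.2), Socs3 (26.6), Cst7 (26.9) and the heat shock score (0.0784). In liquid 1 they were Muc20 (0.193 CPM), Cox6a1 (333) and Hsp90aa1 (157), and in liquid 3 Cst7 (13.9 CPM).

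Monocyte and macrophage markers were higher in hydrogel, 19 of 24. A lower share of megakaryocytes alone would raise markers of every other cell type alike, but the macrophage score minus the mast cell score differed between conditions (exact permutation p = 0.0286, the smallest that 4 against 4 can give), and mast cell markers had a median of −1.33. These lists were picked after their opposite directions were seen, so this p-value does not measure chance. The mast cell fall also varied between libraries: 1 member fell without hydrogel 2, and fry gave an adjusted p of 0.0842. Gata2 of that list is also among the megakaryocyte transcription factors. More RNA of monocytes and macrophages was not tested apart from the macrophage markers. Lyz2 stood at 3536 CPM in hydrogel, although lineage-positive cells were depleted before culture and the BSA gradient selects large cells. Whether this reflects more such cells, carried-over cells or expression in megakaryocytes was not tested.

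Megakaryocyte receptor genes were lower in hydrogel. Within conditions the receptor score fell as the macrophage score rose (Pearson r = −0.94, permutation p = 0.0399 over 576 permutations). Spearman's rho was −0.86 (permutation p = 0.0538), and 1 relation was tested. Without hydrogel 1 and liquid 2, r was −0.79, but the scores stayed centred on condition means that include these libraries. That r therefore mixes in differences between conditions, and how far the relation rests on hydrogel 1 and liquid 2 was not tested. In the other libraries macrophage scores spanned only 1.17 to 1.22 in hydrogel and −1.44 to −0.98 in liquid. With the macrophage score as a covariate, which shares 79.7% of its variance with culture, 0 of 28 receptors fell, and their median went from −0.60 to 0.19. Both rest on the same within-condition relation of receptor and macrophage scores, so they count as 1 observation. It goes with less megakaryocyte RNA where macrophage markers were higher, but other markers also set hydrogel 1 and liquid 2 apart. Of the 8 libraries, liquid 2 had the highest scores of neutrophils (1.09), granulocyte progenitors (0.87), eosinophils (0.94), dendritic cells (1.31) and mast cells (1.54). Hydrogel 1 had the lowest of granulocyte progenitors (−0.79), dendritic cells (−0.82) and mast cells (−1.10). The erythroid score went the other way (−0.32 in liquid 2, 0.37 in hydrogel 1). Whether the relation is particular to macrophages was not tested. Uniform dilution as the whole cause cannot be told apart from gene-specific change. Cochran's chi-square test of heterogeneity over 14 megakaryocyte-restricted genes gave p = 0.0568. These genes are not independent of each other, and variation that they share between libraries widens their standard errors but cancels between genes. The test therefore finds heterogeneity less readily, and its p-value cannot decide. An effect of hydrogel on the megakaryocytes stays open.

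Cholesterol synthesis genes were lower in hydrogel. With the macrophage score as a covariate 15 of the 25 members were still called lower and their median was −0.80 after −1.03, while the receptors no longer fell. That score shares 79.7% of its variance with culture (variance inflation factor 4.92). The conditions come near each other in it only at hydrogel 1 (0.23) and liquid 2 (−0.07). This fit therefore cannot decide whether macrophage content, with the dilution of megakaryocyte RNA that follows it, is the whole cause. Dilution apart from macrophage content cannot be told apart from a change in the pathway: the cholesterol score changed by −0.26 on the log2 scale relative to the megakaryocyte-restricted score, with an exact permutation p of 0.0571. Of the 25 members, 6 fell more than the deepest of the megakaryocyte-restricted genes (−1.16). An effect of hydrogel culture on this pathway stays open as a hypothesis.

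Of the 35 splits of the 8 libraries, 1, the real one, gave as many called genes as 4052, and the highest other gave 1927. The real split also stood alone for genes higher (2096 against 1038), lower (1956 against 1038) and changed at least 2-fold (1381 against 666). A rank of 1 in 35 is the lowest this design can give, so chance is unlikely for these counts but not excluded. Splits that mix the conditions also put their difference into the spread within groups, which holds their counts down. The split with 1927 exchanged hydrogel 1 and liquid 2, which points to a structure of the samples, and every other split called 0 genes. For gene lists, 11 of the 35 splits called at least the real 19, with 25 in the highest other, so chance is not excluded for the number of lists called at the preset correlation.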

How the results depend on the processing

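Leaving out both hydrogel 1 and liquid 2, and the macrophage score as a covariate, were chosen after the results were seen; the other settings were planned. The count of 4052 called genes was 3793 to 4465 under other scalings, filters and tools, 4247 of them with upper-quartile scaling and 3957 after thinning to the smallest library, and none of these calls turned its direction there. The 4465 came from DESeq2, which tested 17478 genes and kept 97.8% of the 4052 calls. On simulated data 17.0% of its 224 calls were false, but few genes were changed there, so that share need not hold for 4465. An adjusted p under 0.01 left 2091, by its construction. Leaving out 1 library gave 2700 (without hydrogel 2) to 4975 (without liquid 2) genes, and 1224 to 2446 lower in hydrogel; fewer samples enter these fits. The replicate number as a block gave 4238 genes, with 93.7% of the calls kept, but the numbers did not meet the rule for pairing, a correlation of deviations over 0.1 in every pair: it was 0.22, 0.33, −0.13 and 0.10 for numbers 1 to 4, so shared preparations stay possible. As a weak hint from the data, 4 of the 8 libraries correlated best with their own number, and some would do so by chance. The highest correlation of deviations between conditions, 0.44, was that of hydrogel 1 and liquid 3, whose numbers differ. Under the block the lists of granule cargo and actomyosin (adjusted p = 0.0435 for both) and of SRF and MRTF targets (0.0447) were also called, and Il1rl1 was not (0.0669). Gene lists called numbered 19 with the preset correlation and 0 with an estimated one. With the macrophage score as a covariate, which shares 79.7% of its variance with culture, 693 genes were called, 368 higher and 325 lower, 432 of them at least 2-fold, and 869 of the 4052 had the opposite sign; of the 194 named genes, 83 lost their call with the same sign and 28 turned, and the cause was not tested. Log2 changes that turned there were Treml1 0.062, Pdgfb 0.063, Gng11 0.25, Myl9 0.44, Itga4 −0.048, Pfkm 0.080, Myh10 −0.48, Mylk 0.41, Mrtfa 0.15, Actb 0.12, Flna 0.70, Tubb1 0.69, Itga2b 0.14, Itgb3 0.41, Gp1ba 0.44, Pf4 0.013, Vwf 0.74, Gata1 0.12, Nfe2 0.26, Fli1 0.066, Lmna 0.88, Cd48 −0.28, Epor 0.0054, Sptb 0.036, Igsf6 −0.40, Csf3r −0.12, Ear6 −0.34 and Blnk −0.35. Of genes that had not passed, Mrtfa was 0.049 with library totals alone and −0.086 to 0.073 without 1 library (lowest liquid 1, highest liquid 3), Flna −0.26 to 0.012 (liquid 2 and liquid 3), and Myh9 −0.055 without both hydrogel 1 and liquid 2. Lists that were not called and turned direction in camera had these adjusted p: tubulins 0.849 with the block, 0.979 with at least 1 CPM and 0.331 without both libraries; interferon 0.979 with at least 1 CPM; focal adhesion 0.795 and dendritic cells 0.516 without both. Over single omissions the adjusted p of lists that turned ranged over 0.646 to 0.999 for tubulins, 0.425 to 0.942 for S phase, 0.555 to 0.997 for interferon, 0.449 to 0.999 for erythroid cells, 0.657 to 0.994 for glycolysis, 0.436 to 0.993 for focal adhesion, 0.318 to 0.997 for podosomes, 0.257 to 0.946 for granulocyte progenitors, 0.135 to 0.983 for neutrophils and 0.322 to 0.983 for eosinophils. Depth limits the genes with few reads, such as Marco, Muc20 and Rxrg.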

Other observations

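All gene groups here were chosen after their values were seen, and none was tested as a group. Of 18 circadian clock genes, 4 rose and 10 fell in hydrogel. Bhlhe41 rose by a log2 change of 1.52 ± 0.15 (SE), along with Bhlhe40, Nfil3 and Nr1d2, while Per3 changed by −1.28 ± 0.13, Hlf by −1.10, Per2 by −1.03 and Rora by −0.99. Of 13 C-type lectin receptor genes, which encode pattern receptors of myeloid cells and platelets, 8 rose and 2 fell: Clec4n rose by 4.07 ± 0.36, Clec4a1 by 2.86 and Clec4e by 2.18, and the falls were Clec9a and Clec1b. Clec7a, 1 of those that rose, is also among the monocyte and macrophage markers, which rose in the same libraries (19 of 24, median log2 change 1.96).

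Of 6 retinoid receptor genes, 2 rose and 3 fell. Rxra rose by a log2 change of 2.63 ± 0.40 and Rara by 2.19 ± 0.38, while Rarb changed by −1.59 and Rarg by −0.41, and Rxrg went from 300 to 4 reads; macrophage markers rose in the same libraries, as given above. Of 8 tested genes of calcium release and amine storage, 0 rose and 4 fell. They were the calcium channel genes Ryr1 (−1.93 ± 0.11), Ryr3 (−1.89) and Itpr1 (−0.43) and the vesicular amine transporter gene Slc18a2 (−1.67 ± 0.15), whereas the serotonin transporter gene Slc6a4 did not pass (−0.09 ± 0.31). In the same libraries 8 of 12 mast cell and basophil markers fell (median −1.33), as did 19 of 28 megakaryocyte receptors (−0.60).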
